A study of Mus musculus with 6 samples.

How the data were processed

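Gonads of mouse embryos at E13.5 were placed in RNAlater, RNA was prepared with the Allprep Micro kit, and 100 ng of total RNA was amplified and labelled with biotin using the NuGen Ovation kit, per the labels' protocols. The deposited values are intensities on a linear scale, 1 column per array, given to 3 significant digits. The authors made them with GCRMA, per the submitters' processing notes, whose version is not given in the sources used here. GCRMA corrects background, normalizes between arrays and summarises the probes of a probe set, so folds between dim values depend on that correction. The quartiles of the 6 columns were close to each other, and all values were above 0. Values per probe and detection calls were not used here.

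Arrays were grouped by the sample titles, 3 control and 3 Dmrt1 null. The table held 45101 probe sets. GEO's platform annotation gave 34958 of them 1 gene symbol, 932 several and 9211 none. Of those with 1 symbol, 34754 matched a RefSeq gene (assembly GRCm38.p6) by Entrez ID, and 0 symbols changed. No gene was named from a probe set with several symbols. The RefSeq table was used for names and gene order alone, because the build behind the arrays is not given in the sources used here.

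Intensities were taken to log2 with no added constant. Probe sets with a mean log2 value of at least 4 over the 6 arrays were kept, 22082 in all, with 11874 gene symbols. They included 32 control probe sets of the array. Each was fitted with limma 3.58.1 in R 4.3.3, with the group as the only term, eBayes with an intensity trend and Benjamini-Hochberg adjustment over all kept probe sets. Tests were two-sided and calls were made at an adjusted p under 0.05. Differences are null minus control on the log2 scale, and folds are their antilogs. Residual degrees of freedom were 4 per probe set, and 7.91 with the shared prior.

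The 23 gene lists of cell types and pathways were fixed before the data were examined. Each was tested with camera in limma with a preset correlation of 0.01 and 1 probe set per gene, the brightest, with Benjamini-Hochberg adjustment over the lists. Camera compares a list with the other genes. The test was repeated with an estimated correlation and with fry, which asks whether the genes of a list move on balance 1 way.

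The genes named were set by a rule before the data were examined. They are the Dmrt1 probe set, up to 10 genes per direction with the largest change among called genes whose groups did not overlap, and from each list the called members, or else the members with the smallest p. Places left over went to genes of smallest p with an absolute log2 difference of at least 1 and groups that did not overlap, which 6 genes met among those higher. Some genes of interest were fixed by name, such as Pou5f1 and Gdnf. Other list members given as examples, and Kank1, Smarca2 and Dmrt3, were chosen after their values were seen.

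The test was tried on simulated data with the means and spread of these arrays. Of 100 probe sets changed by 1 on the log2 scale 64% were called, and of 100 changed by 2 there were 94% called, with 10 false calls. With no change simulated, 0 of 22082 probe sets were called. The noise was drawn independently for each probe set, with no structure shared over probe sets as the real arrays have. These counts therefore do not measure false calls in the real arrays. The shares called also rest on 200 probe sets being changed at the same time.

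The alternatives fixed beforehand were no filter, a filter at a mean of 6, quantile normalization, median centring, 16 added to the intensities, eBayes without the trend or with robust estimation, array weights, the replicate number as a block, leaving out each array, other thresholds, 1 test per gene, the mean over probe sets, and leaving out probe set types prone to shared binding. A random block for the leading animal number in the descriptions was fixed too but could not be fitted, because 5 levels over 6 arrays gave no estimate of the correlation. Control replicate 3 and null replicate 2 share that number with different letters after it, what it stands for is not given in the sources used here, and no number is shared within a group. A covariate for cell composition, and the GDNF list without Ret, were added after seeing the data. Between any 2 arrays, 301 to 451 of the 45101 values were equal, so none was a copy of another.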

Results

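Gene expression was measured with oligonucleotide arrays in testes of mouse embryos at E13.5, a stage shortly after the testis has formed, on a background outcrossed to the 129S6/SvEvTac strain. Dmrt1 encodes a transcription factor of the DM domain family that is expressed in Sertoli cells and germ cells of the fetal testis. The 6 arrays comprised 3 control and 3 Dmrt1 null testis samples, each labelled as a separate biological replicate. The labels disagree on the genotypes. The titles call the controls wild type, whereas their descriptions and genotype entries and the design text of the series give them as heterozygous for Dmrt1. The null samples are homozygous null by title, description and design text, whereas their genotype entry names homozygous floxed alleles. The groups are called control and null here. Each array gave an intensity for 45101 probe sets, with array medians of 14.6 to 14.8 and upper quartiles of 224 to 233. The number of arrays, 3 per group, limits the precision of every comparison. The ratio of 3' to 5' signal of the Actb control probe sets was 2.75 in null replicate 3 and 1.91 to 2.15 in the other arrays.

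The design asks how loss of Dmrt1 changes gene expression in the fetal testis of a strain in which the mutants often form teratomas. The Dmrt1 transcript itself followed the labels. Its probe set gave intensities of 696, 1030 and 796 in control replicates 1, 2 and 3, and of 48.4, 26.9 and 23.8 in null replicates 1, 2 and 3. Dmrt1 was 26.4-fold lower in the null testes (95% confidence interval 16.9 to 41.4, n = 3 per group). The log2 difference of null minus control was -4.72 with a standard error of 0.28, and limma gave a Benjamini-Hochberg adjusted p of 0.00388. Leaving out control replicate 3 gave a Dmrt1 difference of -4.75 with a limma adjusted p of 0.0558. The position of this probe set relative to the deleted part of Dmrt1 is not given in the sources used here.

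Few other transcripts passed the test. Besides Dmrt1, 5 genes fell in the null testes and none rose by limma at an adjusted p of 0.05, among 22082 probe sets tested. The genes that fell were Cst9, a cystatin-related gene of fetal Sertoli cells, Tox2, an HMG-box factor, H2-Aa, an MHC class II alpha chain, Islr2, a leucine-rich repeat membrane protein, and AU015836. At an unadjusted p under 0.05, limma gave 608 probe sets higher and 725 lower in the null. Regrouping the same arrays into equal groups that mix the genotypes, done after the results were seen, gave 190 to 3044 such probe sets. Counts of 1815, 1994 and 3044 exceeded the 1333 of the genotype grouping, and the rest were 952 or lower. The count of 1333 therefore does not by itself set the genotypes apart. The control and null groups did not overlap at 2824 probe sets, which is 12.8% of those tested, against 10% given by chance.

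The 5 genes differed in level and in size of change. Cst9 was abundant, with an intensity of 3147 ± 276 in controls and 1063 ± 177 in nulls (mean ± SD, n = 3 each). Its log2 difference was -1.58 with a standard error of 0.13, a 2.98-fold lower level at a limma adjusted p of 0.0271. AU015836 was 2.10-fold lower, with intensities of 1009 ± 17.9 and 481 ± 30.3 (mean ± SD, n = 3 each) and a limma adjusted p of 0.0307. Tox2 was 4.12-fold lower, with intensities of 307 ± 73.2 and 73.5 ± 8.91 (mean ± SD, n = 3 each) and a limma adjusted p of 0.0338. This Tox2 probe set is of a type that can bind related transcripts, and the other Tox2 probe set, below the filter and near background, had a log2 difference of 0.15. H2-Aa was 4.71-fold lower, from 39.7 ± 5.88 to 8.50 ± 1.93 (mean ± SD, n = 3 each), at a limma adjusted p of 0.0334. A second tested H2-Aa probe set had a log2 difference of -1.22 and a limma adjusted p of 0.197, and each H2-Aa probe set that differed is of a type that can bind related transcripts. Islr2 was 3.19-fold lower, from 50.4 ± 7.50 to 15.7 ± 1.53 (mean ± SD, n = 3 each), at a limma adjusted p of 0.0459. The null values of H2-Aa and Islr2 lay below or close to the array medians, and adding 16 to every intensity gave log2 differences of -1.18 and -1.06 in place of -2.24 and -1.67. Limma called 1 gene without control replicate 1, 1 without control replicate 2, 0 without control replicate 3, 4 without null replicate 1, 2 without null replicate 2 and 1 without null replicate 3. Dmrt1 alone was called without the intensity trend, and Islr2 was not called with quantile normalization, with 16 added or with no filter. The filter at a mean log2 value of 6 removed Islr2 and H2-Aa before the test, since their probe sets had means of 4.81 and 4.18.

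Further genes showed log2 differences of at least 1 and groups that did not overlap, but were not called. Lower in the null were Jakmip2 at -2.38 (standard error 0.26, limma adjusted p = 0.0527), Ret, the receptor tyrosine kinase for ligands of the GDNF family, at -2.34 (standard error 0.28, limma adjusted p = 0.0979), Fgf13 at -1.43 and Nmrk1 at -1.03. With 16 added to every intensity, the difference was -1.32 for Jakmip2, -1.56 for Ret, -1.34 for Fgf13 and -0.76 for Nmrk1. Below the filter, another Ret probe set was at -1.41 and 2 other Jakmip2 probe sets near background were at -0.14 and 0.05. A second tested probe set of Nmrk1 had a difference of 0.47, opposite in sign. Higher in the null were Ctrb1, a pancreatic protease precursor, at 1.67, Cdhr1 at 1.17, Zar1, an oocyte factor, at 1.16, Cemip at 1.13, Dmrt2 at 1.09 and Tmem114 at 1.07, with limma adjusted p of 0.654 to 0.773. With 16 added, the difference was 0.66 for Dmrt2, 0.67 for Zar1, 0.80 for Tmem114 and 0.88 for Cdhr1. It was 0.95 for Cemip and 1.63 for Ctrb1 in that setting. Without null replicate 1 the difference of Cdhr1 was 0.64.

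**Figure D1:**
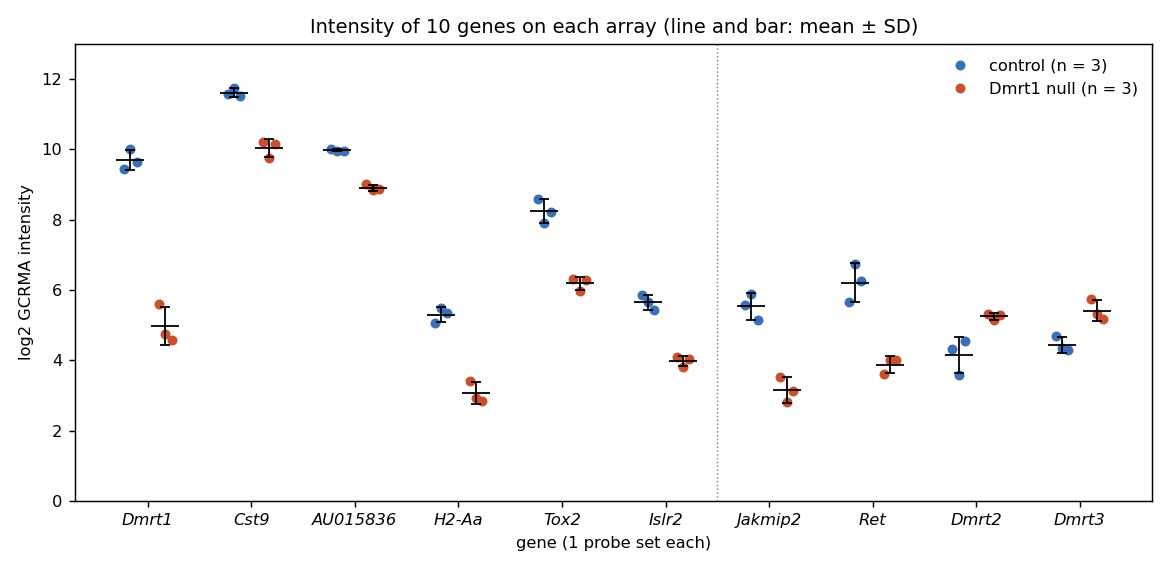
Log2 intensity of 10 genes on each of the 6 arrays, with 1 point per array and lines for the mean ± SD of each group (n = 3). The dotted line separates the 6 genes called by limma, Dmrt1 among them, from 4 genes that were not called, and the groups do not overlap for any gene shown.

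Of 23 gene lists chosen before the data were examined, camera in limma called 5 with a preset correlation between genes of 0.01. Macrophage and leukocyte markers, GDNF signalling genes, germ cell markers and immediate early genes were lower in the null testes as groups, and mitotic cell cycle genes were higher. None of the 5 was called with an estimated correlation. That correlation was 0.32 for germ cell markers, 0.25 for macrophage and leukocyte markers and 0.09 for mitotic cell cycle genes. It was 0.01 for immediate early genes and -0.05 for GDNF signalling genes. The shifts were small, with list medians between -0.24 and 0.07 on the log2 scale. No member of these 5 lists was called over all probe sets.

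Germ cell markers were lower at 15 of 19 measured members, with a median of -0.22 (limma camera adjusted p = 0.00542, and adjusted p = 0.614 with an estimated correlation). Tdrd5 at -1.42 and Piwil2 at -0.60, both of the piRNA pathway, had the smallest p, and ranged from -2.06 to -0.76 and from -0.79 to -0.34 when single arrays were left out. The RNA-binding proteins Ddx4 and Dazl had differences of -0.22 and -0.18, and Rhox9 one of 1.05. The median level of the list was 0.63 in control replicate 2 and between -0.32 and 0.09 in the other 5 arrays. No germ cell marker was called adjusted over the list alone, a count of 0. The list's limma camera adjusted p was 0.595 without control replicate 2, where its median was 0.02, and 0.0653 without null replicate 3, where its median was -0.14. Without control replicate 1 the median was -0.40. With a score of endothelial, erythroid and Leydig transcripts as a covariate, chosen after seeing the data, the list's limma camera adjusted p was 0.109.

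GDNF signalling genes were lower at 10 of 12 members, with a median of -0.17 (limma camera adjusted p = 0.00490, and adjusted p = 0.369 with an estimated correlation). Adjusted over the list alone, Ret and Sdc4, a syndecan, were lower, at -2.34 and -0.64. The co-receptor Gfra1 and the ligand Gdnf had differences of -0.28 and 0.10, neither called. This list was chosen with knowledge that published work on this mutant discusses the pathway, so it is not fully independent of the study. The median was -0.26 without control replicate 3 and -0.27 without null replicate 2. Without Ret, an alternative added after seeing the data, the limma camera adjusted p of GDNF signalling and its spermatogonial targets was 0.0476.

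Mitotic cell cycle genes were higher at 31 of 39 members, with a median of 0.07 (limma camera adjusted p = 0.00637, and adjusted p = 0.583 with an estimated correlation). Ccne1 at 0.38, Cdc25c at 0.27 and Cdk4 at 0.11 were examples, none called. Ccnd1 had a difference of -0.08. The count adjusted over the list alone was 0. The limma camera adjusted p was 0.207 without control replicate 2, 0.0968 without null replicate 2 and 0.0777 without null replicate 3 for the mitotic cell cycle genes. Their median was 0.042 without control replicate 2 and 0.11 without control replicate 3. The limma camera adjusted p of this list was 0.127 with the score of endothelial, erythroid and Leydig transcripts. With an eBayes fit without an intensity trend that adjusted p was 0.05004. Cell cycle inhibitors had a median of -0.06 (-0.12 to -0.011 with single arrays left out) and were not called, with Cdkn1b at -0.07, Rb1 at -0.51 and Gadd45g at 0.45.

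Macrophage and leukocyte markers were lower at 13 of 16 members, with a median of -0.24 (limma camera adjusted p = 0.00203, and adjusted p = 0.583 with an estimated correlation). The mannose receptor Mrc1 at -0.54 and Adgre1 at -0.40 had the smallest p. Adjusted over the list alone, 0 members were called, and without control replicate 3 the limma camera adjusted p of the macrophage and leukocyte markers was 0.0910. Immediate early and stress response genes were lower at 14 of 17 members, with a median of -0.13 (limma camera adjusted p = 0.00542, and adjusted p = 0.369 with an estimated correlation). Fos at -0.61 and Ier3 at -0.46 had the smallest p, and 0 members were called adjusted over the list alone. Without null replicate 2 the limma camera adjusted p of the immediate early and stress response genes was 0.0607 and their median -0.038, and with the score of endothelial, erythroid and Leydig transcripts the adjusted p was 0.0596. Without null replicate 3 their median was -0.081.

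**Figure D2:**
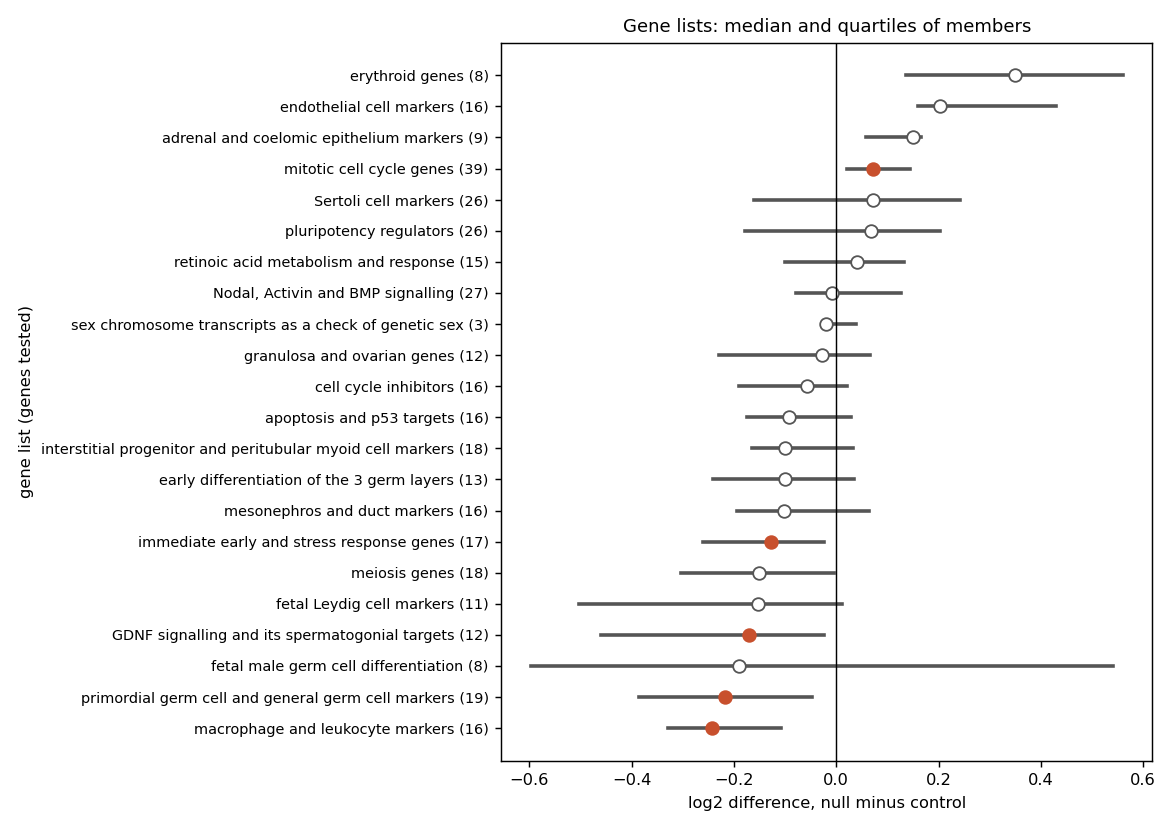
Log2 difference, null minus control, for each gene list, with a point at the median of its tested members, a line over their quartiles, and filled points for the 5 lists at a limma camera adjusted p under 0.05 with the preset correlation. The DM domain family is not drawn, and the called lists have medians from -0.24 to 0.07.

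The pluripotency regulators were not called, with 14 members higher and 12 lower (limma camera adjusted p = 0.955). Pou5f1, Nanog and Sox2, core factors of pluripotent cells, had differences of 0.20 ± 0.26, 0.07 ± 0.11 and -0.13 ± 0.12 (standard error, n = 3 per group). Tfap2c, a factor of early germ cells, was at 1.00 and Tbx3 at -0.19, neither called. The list's median of 0.07 and mean of 0.06 lay above 0, whereas camera placed it lower, and the median lay between -0.0091 and 0.12 when single arrays were left out. This list too was chosen with knowledge of published work on the mutant, and 0 members were called adjusted over the list alone.

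Sertoli cell markers did not shift as a group (limma camera adjusted p = 0.860), with 1 of 26 members called, Cst9, which fell. Adjusted over the list alone, Cst9 and Aard were lower, Aard at -0.43. At an unadjusted limma p under 0.05, 3 members were higher, Nr0b1 at 0.55, Nr5a1 at 0.54 and Tesc at 0.52, and 4 were lower, Cst9, Aard, Hsd17b1 at -0.83 and Sox8 at -0.59. Sox9, which directs Sertoli cell fate, was at -0.34 ± 0.32, and Amh, the anti-Müllerian hormone, at 0.06 ± 0.14 (standard error, n = 3 per group). The list's median was 0.07 and its mean -0.03, and camera placed it lower. Single arrays left out gave medians of 0.0040 to 0.11.

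No list of later germ cell stages was called. Meiosis genes had 13 of 18 members lower and a median of -0.15 (limma camera adjusted p = 0.170), with Ythdc2 at -0.33 and Sycp1 at -0.92, the latter between -1.58 and -0.34 when single arrays were left out. The median of the meiosis genes was 0.073 without control replicate 2 and -0.34 without control replicate 1. Stra8, a retinoic acid target needed for meiosis, lay below the expression filter, with a difference of -0.65 that rested on control replicate 2. Log2 levels of Stra8 were 3.04, 4.23 and 3.04 in control replicates 1, 2 and 3 and 2.71, 2.72 and 2.94 in null replicates 1, 2 and 3. Genes of fetal male germ cell differentiation had a median of -0.19 and a mean of -0.11 (limma camera adjusted p = 0.919), and a median of 0.074 without control replicate 2, though Nodal, Lefty1 and Lefty2 were at 0.50, 0.67 and 0.68. The Nodal, Activin and BMP list had a median of -0.01 and a mean of 0.05, and camera placed it higher at a limma adjusted p of 0.919. Its member Fst was at -0.58. Genes of retinoic acid metabolism had a median of 0.04, with Rxrb at 0.24 and Aldh1a3 at -0.39, and apoptosis genes one of -0.09, with Pmaip1 at -0.63 and Mdm2 at -0.17. Early differentiation genes of the 3 germ layers had a median of -0.10, with Pax6 at 0.53 and Dcx at -0.45, and medians of -0.41 without null replicate 1, -0.37 without control replicate 1 and 0.091 without control replicate 3. With single arrays left out, the median ranged from -0.029 to 0.057 for the Nodal list, from -0.031 to 0.11 for retinoic acid genes and from -0.11 to -0.013 for apoptosis genes.

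Markers of other cell types were not called with all 6 arrays and the settings used throughout, although each of these lists was called under at least 1 alternative. The medians were -0.15 for fetal Leydig cells, 0.20 for endothelial cells, 0.35 for erythroid genes, -0.10 for interstitial progenitors and peritubular cells, -0.03 for granulosa and ovarian genes, -0.10 for mesonephros and duct markers and 0.15 for adrenal and coelomic epithelium markers. Leaving out single arrays moved the median between -0.66 and 0.06 for Leydig cells, -0.19 and 0.53 for endothelial cells, -0.07 and 0.79 for erythroid genes and -0.19 and 0.40 for the adrenal list. The medians then lay between -0.098 and -0.031 for the interstitial list, -0.12 and -0.048 for the granulosa list and -0.16 and 0.015 for the mesonephros list. Limma camera adjusted p ranged from 0.0784 for the interstitial list to 0.407 for the Leydig list. Cyp17a1, a steroidogenic enzyme of Leydig cells, was at -0.62 ± 0.63, and the embryonic globin Hbb-bh1 at 0.99 ± 0.58 (standard error, n = 3 per group). Single arrays left out moved Cyp17a1 between -1.30 and -0.043 and Hbb-bh1 between 0.40 and 1.69. Adjusted over the list alone, Ret was lower among the mesonephros markers. Endothelial levels, as the median over members of log2 intensity minus the mean of the 6 arrays, were -1.05 in control replicate 2 and -0.51 in null replicate 1, against 0.36 and 0.23 in control replicates 1 and 3 and 0.25 and 0.57 in null replicates 2 and 3. Leydig levels were -0.42, 0.18 and 0.50 in control replicates 1, 2 and 3 and 0.64, -0.38 and -0.55 in null replicates 1, 2 and 3, so both varied more within the groups than between them.

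**Figure D3:**
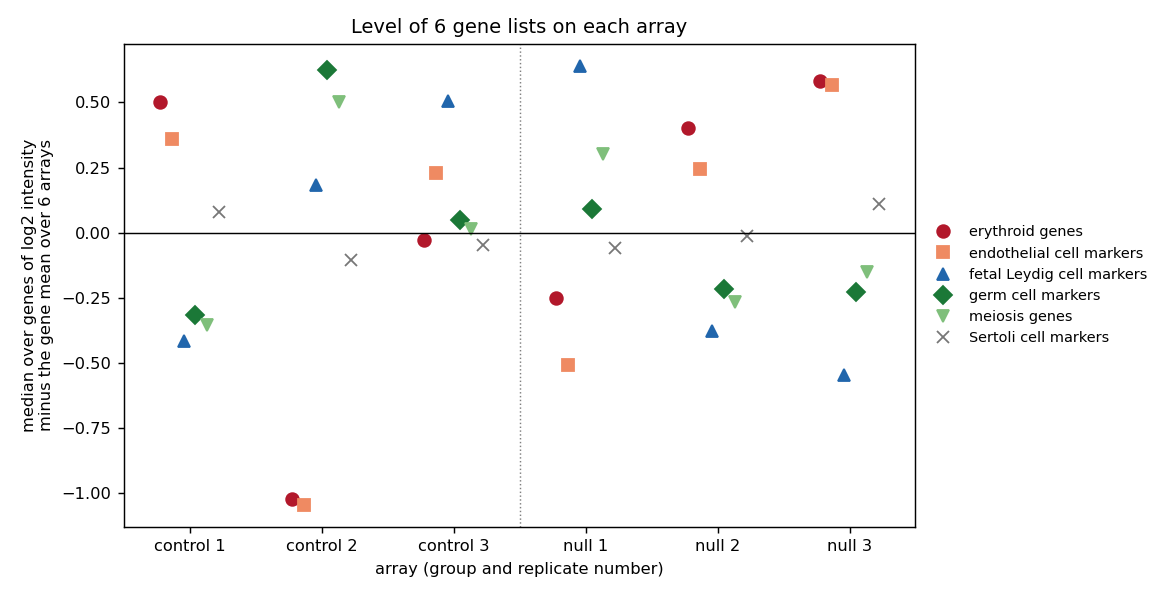
Level of 6 gene lists on each array, as the median over genes of log2 intensity minus the gene's mean over the 6 arrays, with 1 symbol per list. Control replicate 2 and null replicate 1 have the lowest endothelial levels, -1.05 and -0.51.

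In the DM domain family, Dmrt1 fell and the other 3 measured members were not called over all probe sets. Adjusted over the list alone, Dmrt1 was lower and Dmrt2 and Dmrt3 were higher, at 1.09 ± 0.25 and 0.96 ± 0.21 (standard error, n = 3 per group). Dmrt3 and Dmrt2 are the next genes beside Dmrt1 in the RefSeq gene order, and Kank1 and Smarca2, which flank these 3, had differences of 0.29 and 0.21. Another tested Smarca2 probe set was at -0.11, and a Kank1 probe set below the filter was at -0.05. The family's median was 0.39 and its mean -0.71, and camera placed it lower at a limma adjusted p of 0.919. The Y-linked transcripts Kdm5d and Eif2s3y, from the list set up as a check of sex, had differences of 0.10 and -0.02. The median of that list was -0.02 (-0.023 to 0.12 with single arrays left out), its mean 0.02, and camera placed it higher at a limma adjusted p of 0.955. Differences between groups do not by themselves give the sex. On each array the tested Kdm5d and Eif2s3y probe sets had log2 levels of at least 9.46 and 11.27. Xist probe sets, below the filter, lay at 1.67 to 2.45. Other Kdm5d and Eif2s3y probe sets also lay below the filter.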

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

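The tests of H2-Aa, of Dmrt2 and Dmrt3, of the germ cell markers and of the splits of the arrays were chosen after the results were seen, whereas leaving out arrays and dropping the filter were fixed beforehand.

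A further probe set of H2-Aa, too dim to enter the test, was also lower in the null testes, with a log2 difference of -1.89 and a limma adjusted p of 0.0280 when no filter was used. A fault of a single H2-Aa probe set is argued against, unless these probe sets share probes, which was not checked. The smallest difference among the other H2-Aa probe sets above a mean log2 value of 3 was -1.22, with a 95% interval that ends at -0.87. Another H2-Aa probe set, near background, was at -0.12. Fewer leukocytes in general are argued against as well, since the median of the macrophage and leukocyte markers was -0.24, above the upper bound of -1.75 for H2-Aa by more than the spread of its members. Other transcripts of cells rich in MHC class II had differences of -0.09 for Cd74, -0.04 for H2-Eb1 and -0.19, 0.04 and -0.00083 for the H2-Ab1 probe sets, but all lay near background in both groups and below the filter, so they exclude no loss of such cells. A rarer cell type rich in MHC class II, a strain difference at the MHC, binding of related transcripts and an effect of the Dmrt1 genotype remain open.

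Dmrt2 and Dmrt3, the next genes beside Dmrt1, were higher in the null at 1.09 and 0.96 without passing the adjustment over all probe sets, and at 0.66 and 0.63 with 16 added to the intensities. Different shares of erythroid, endothelial and Leydig cells are argued against, since the lower 95% bounds stayed at 0.46 or above with a score of their markers as a covariate, and so is the higher 3' to 5' ratio of null replicate 3, since without it the bounds stayed at 0.35 or above. DNA of another strain carried along with the Dmrt1 mutation cannot be told apart from an effect of the mutation, since 4 of 40 flanking genes, Aldh1a7, Pgm5, Glis3 and Insl6, had an unadjusted p under 0.05 and 26.2% of 10000 random runs of adjacent genes held as many. That count took 1 probe set per gene, and the neighbour Pum3 had 1 probe set at 0.54 and 2 others at -0.01 and -0.03. Shares of other cell types and an effect of losing Dmrt1 or of the altered locus on its neighbours remain open as well. Chance is not excluded either, since both genes were taken up after their values were seen. The 95% bounds given here are not adjusted for that choice.

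The germ cell markers were lower as a list, but this depended on single arrays. Without control replicate 2 the adjusted p from camera in limma was 0.595 and the list's median 0.02, where it was -0.22 with all arrays. The range over the arrays left out was 1.8e-06 to 0.595. Uneven cell makeup of single samples is a candidate explanation for the shift, and an effect of the genotype on germ cells remains open, untested by these data.

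With 10 splits of the 6 arrays into 3 and 3, no share under 0.05 can be reached. The real split called 6 probe sets and the highest other split 232, so 2 of the 10 splits gave as many. For gene lists the real split called 5 and the highest other 8, and 5 of the 10 splits gave as many. The split with 232 set control replicate 1 and null replicates 2 and 3 against the others, which points to a structure of the samples that crosses the genotypes.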

How the results depend on the processing

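The cell composition covariate and the GDNF list without Ret were chosen after seeing the data, and the other alternatives were fixed beforehand. The cause of each change was not tested, unless fewer arrays or fewer probe sets account for it. Dim signal limits folds, among them those of H2-Aa, Islr2, Jakmip2, Ret, Dmrt2, Dmrt3, Zar1, Pax6, Dcx, Cdhr1, Tmem114, Cemip and Nmrk1. With 16 added, log2 differences were 0.66 for Dmrt2, 0.67 for Zar1, 0.30 for Pax6 and -0.25 for Dcx. They were 0.88 for Cdhr1, 0.80 for Tmem114, 0.95 for Cemip and -0.76 for Nmrk1.

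The direction of Dmrt1 was kept in every alternative. Probe sets called numbered 6, and 4 to 8 with no filter, a filter at 6, quantile normalization, median centring, a pseudocount of 16, robust eBayes, array weights, both other thresholds, 1 test per gene and the composition covariate, which called 1 higher. Jakmip2 was gained with median centring, robust eBayes, array weights, an adjusted p limit of 0.10, 1 test per gene and the composition covariate. Ret was gained with array weights and with that limit. Neither was called with any single array left out. Without the eBayes trend 1 was called, Dmrt1. Without the probe set types prone to shared binding 3 were called. The called probe sets of H2-Aa and Tox2 are of these types and were left out there. This does not account for the whole fall from 6 to 3, and the cause of the rest was not tested. Leaving out single arrays gave 0 to 4 calls and Dmrt1 transcript differences of -5.03 to -4.52. No pairing of the arrays by replicate number was seen. The deviations of same-numbered arrays correlated at -0.59, -0.34 and 0.14 across probe sets, and not every array correlated best with its own number. The variation that crosses the genotypes also enters these correlations, so a weaker pairing is not excluded. With the number as a replicate block 0 were called, with 816 at an unadjusted limma p under 0.05, and the Dmrt1 transcript stayed at -4.72 with a limma adjusted p of 0.200. The random block for the animal number was not run, as it could not be fitted.

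Gene lists called numbered 5, and 8 with a filter at 6 (with the DM domain family through Dmrt1 alone), 3 with the composition covariate, 0 with an estimated correlation, 0 with fry and 3 to 11 without single arrays. Estimated correlation and fry gave limma adjusted p of 0.614 and 0.836 for germ cell markers, 0.583 and 0.563 for mitotic genes, 0.369 and 0.129 for GDNF signalling, 0.583 and 0.710 for macrophage markers and 0.369 and 0.710 for immediate early genes. The composition covariate gave 0.109 for germ cell markers, 0.127 for mitotic genes and 0.0596 for immediate early genes, and eBayes without trend 0.05004 for mitotic genes. Without single arrays the ranges were 1.8e-06 to 0.595 for germ cell markers, 0.000557 to 0.207 for mitotic genes, 0.00135 to 0.0204 for GDNF signalling, 9.6e-05 to 0.0910 for macrophage markers and 0.00144 to 0.0607 for immediate early genes.

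Test directions that changed belonged to results that were not called, although the median of the called germ cell list turned to 0.02 without control replicate 2. By limma adjusted p, array weights turned the pluripotency (0.428), fetal male germ cell (0.723), retinoic acid (0.895), Sertoli (0.723) and sex chromosome (0.909) lists. They gave Gfra1 0.14 and Eif2s3y 0.014. The composition covariate turned the pluripotency (0.668), retinoic acid (0.975), Leydig (0.826), endothelial (0.806), erythroid (0.967) and early differentiation (0.805) lists, with Ccnd1 at 0.00098, Gdnf at -0.050 and Eif2s3y at 0.047. No trend turned the retinoic acid list (0.982). A filter at 6 turned the pluripotency (0.930), Nodal (0.934) and Sertoli (0.783) lists, and no filter the pluripotency (0.912) and sex chromosome (0.912) lists. Fry turned the pluripotency (0.859) and fetal male germ cell (0.836) lists, median centring the pluripotency list (0.987), and the replicate block the DM domain list (0.948). The mean over probe sets turned the fetal male germ cell (0.901), Nodal (0.671) and sex chromosome (0.855) lists. Leaving out types prone to shared binding turned the fetal male germ cell (0.549) and Nodal (0.940) lists.

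Without single arrays, Amh ranged from -0.0011 to 0.16, Ccnd1 from -0.18 to 0.025, Ddx4 from -0.40 to 0.018, Eif2s3y from -0.11 to 0.11, Gdnf from -0.18 to 0.34 and Gfra1 from -0.60 to 0.042. Other named genes, none called, kept their sign but moved by over 1.5 times. They ranged from -0.81 to -0.37 for Fst, -0.95 to -0.38 for Pmaip1, -0.66 to -0.17 for Aldh1a3, 0.16 to 0.36 for Rxrb, 0.36 to 0.83 for Pax6 and -0.64 to -0.18 for Dcx. They ranged from 0.00017 to 0.46 for Pou5f1, 0.0093 to 0.13 for Nanog, -0.24 to -0.057 for Sox2, 0.64 to 1.38 for Tfap2c, -0.55 to -0.018 for Sox9, -0.27 to -0.10 for Dazl, -0.17 to -0.014 for Cdkn1b, -0.65 to -0.36 for Mrc1, -0.48 to -0.26 for Adgre1 and 0.0054 to 0.15 for Kdm5d. Adjusted p of lists that turned then ranged from 0.657 to 0.994 for the DM domain family, 0.450 to 0.994 for Nodal, 0.360 to 0.994 for Sertoli, 0.0123 to 0.994 for adrenal, 0.0580 to 0.988 for early differentiation, 0.000557 to 0.931 for endothelial and 0.00369 to 0.931 for erythroid. They were 0.000557 to 0.988 for Leydig, 0.646 to 0.994 for fetal male germ cell, 0.00163 to 0.670 for meiosis, 0.392 to 0.994 for pluripotency, 0.563 to 0.994 for retinoic acid and 0.672 to 0.994 for sex chromosome lists.

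Some lists not called with all arrays were called in the same direction under an alternative. By limma adjusted p, the interstitial list was called with a filter at 6 (0.0462), array weights (0.0104), without control replicate 2 (0.00278) and without null replicate 1 (0.0362), and the granulosa list with a filter at 6 (0.0462). The mesonephros list was called with the replicate block (0.0346), without control replicates 1 (0.00976) or 3 (0.00724) and without null replicate 1 (0.0204). The Leydig list was called with array weights (0.0162) and without control replicate 1 (0.0492) or null replicate 1 (0.000557), and the adrenal list with the composition covariate (0.00387) and without control replicate 2 (0.0123). Endothelial genes were called without control replicates 1 (0.00206) or 3 (0.00592) or null replicate 1 (0.000557), and erythroid and meiosis genes without control replicate 1 (0.00369 and 0.00163) or null replicate 1 (0.0204 and 0.00339). A filter at 6 left Dmrt1 as the only member of the DM domain family, so its call there is that of Dmrt1 and not of a family.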

Other observations

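The genes and values in this part, and the test with a composition score, were chosen after the results were seen.

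The leading axis of variation crossed the genotypes. The first principal component held 44.9% of the variance and placed control replicate 2 and null replicate 1 at 33.6 and 31.8, and control replicate 1 and null replicates 2 and 3 at -22.8, -19.3 and -27.1, with control replicate 3 at 3.79. Along it, endothelial and erythroid transcripts were low where the component was high. Erythroid levels were -1.03 in control replicate 2 and -0.25 in null replicate 1, against 0.50 in control replicate 1, 0.40 in null replicate 2 and 0.58 in null replicate 3.

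Among transcripts of secreted proteases, Ctrb1 was at 1.67. A pair of Klk1 probe sets was at 1.07 and 0.85 and another Klk1 probe set at 0.23. Limma called Ctrb1 higher at an adjusted p of 0.0214 with the cell composition score as a covariate, an alternative added after seeing the data, and its adjusted p over the alternatives ranged from 0.0214 to 0.961. Other pancreatic enzyme genes, not called and not tested as a group, had Cpa1 at 0.31, Cela3b at 0.37, Pnliprp2 at 0.74 and Clps at -1.07.

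Of the Dmrt3 probe sets below the filter, 2 were higher at 0.68 and 0.38 and another was at -0.06. A probe set of Tox, a relative of Tox2, was at -0.81 and was not called.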
